A study of Escherichia coli with 16 samples.

How the data were processed

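RNA was sequenced from Escherichia coli MG1655 and a mutant lacking hfq, without phage and at 0, 10 and 20 min after addition of P1vir, in 16 libraries, 2 for each of 8 groups. Per the labels, cells grew in LB with 10 mM CaCl2 at 37 degrees C to an OD600 of 0.2 and received phage at a multiplicity of infection of 10. Samples of 500 µl went through RNAprotect, RNeasy columns, ribosomal RNA reduction and TruSeq Stranded libraries, read as pairs of 50 bp. The deposited count tables hold read pairs mapping uniquely to each of 4497 host genes and 117 phage genes, per the deposited description of the files. The deposited summary tables give the percent of read pairs passing quality filtering, the rRNA fraction, PCR duplicates and mapping, per the file headers, with the denominator of each percent not given. The submitters' processing notes name Trimmomatic, Bowtie2, Picard, featureCounts, Subread, DESeq2, edgeR and DESeq without versions or order. The strand setting of the counting and the genome build are not given in the sources used here. Deposited RPM tables were left out because the counts behind them are available.

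Host gene symbols came from a RefSeq table of locus tags, in which 4487 of 4497 identifiers matched. Each library had 14349443 to 19203278 read pairs, 327077 to 691512 host counts and 3561 to 3937 host genes detected; duplicates made up 21.01 to 28.33%. Read pairs, percents and counts were taken as deposited, and all 16 libraries were kept. Group, comparison, test, gene list and naming choices were made before the data were examined, except that dinG and rbfA were named after their values were seen.

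Host counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a count minimum of 10 (2560 genes, with rRNA and tRNA genes included), scaled by TMM and fitted with a quasi-likelihood model of the 8 groups, which leaves 8 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each of 12 comparisons and called below 0.05. The comparisons were mutant against wild type in each condition, each time against no phage within each strain, and the difference between the strains' changes at 10 and 20 min. CPM are TMM-scaled, and SDs are between the 2 libraries of a group.

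Phage counts were fitted in the 12 infected libraries with library sizes and scaling from the host genes, over 46 tags with at least 10 counts in at least 2 libraries, with 6 residual degrees of freedom. Phage share is the percent of host plus phage counts on phage genes. Its 95% intervals are exact binomial (Clopper-Pearson) and a count of 0 is given as a limit of 3 counts; both cover counting error alone. Phage tags with a mean of at least 5 counts in the 4 uninfected libraries were treated as background.

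Host gene lists, 27 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted within each comparison, and again with a correlation estimated for each list. Called members were counted over all tested genes and with adjustment over the list alone. Another 7 lists of phage functions matched no phage tag. Genes named in the text were hfq; the 10 largest rises and falls per comparison among called genes with a log2 fold change of at least 1, a mean of at least 10 CPM in the higher group, groups that do not overlap and a symbol not starting with y; and up to 4 called members per list with the smallest adjusted p. Not every gene given by this rule is printed. Genes with 1 to 3 counts in a group, insertion sequences and antisense genes were not named.

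Replicates 1 and 2 are labelled experiment 1 and 2 in each group, so the numbers pair the libraries by experiment. Deviations from the group means correlated at 0.248 to 0.38 between mutant groups (median 0.354, above 0.1 in 6 of 6 pairs), at 0.002 to 0.179 between wild-type groups (median 0.057, 1 of 6) and at -0.075 to 0.156 between the strains (median 0.041, 3 of 16).

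Alternatives were DESeq2 1.42.0, RLE or library size scaling, no filter on low counts, a log2 fold change of at least 1, a replicate block, 0 min as the reference, other phage scalings and filters, and each library left out in turn. Added after the data were seen were fits without rRNA and tRNA genes, without mutant 20 min replicate 2 throughout, with a block within each strain, and without the background tags.

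The procedure, without the replicate block, was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 2560. For mutant against wild type without phage it recovered 52% of 2-fold and 86% of 4-fold changes with 7 false calls of 145. For the wild type at 20 min these were 52% and 88% with 7 of 147, for the mutant at 20 min 49% and 85% with 9 of 143, and for the difference between strains at 20 min 20% and 76% with 6 of 102. For mutant against wild type at 20 min over 46 phage genes it recovered 0% of 12 changed 2-fold and 16.7% of 12 changed 4-fold. A list of 25 members with a planted shift was called in each of the 4 host comparisons simulated, and 0 of 27 lists without one. Simulated genes were drawn independently of each other, so this does not test the error rate for lists whose members vary together.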

Results

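Total RNA was sequenced from Escherichia coli K-12 strain MG1655 and from a derivative lacking hfq, the gene of an RNA chaperone through which many small regulatory RNAs act on messenger RNAs. Cultures grown at 37 degrees C to an OD600 of 0.2 were sampled without phage and at 0, 10 and 20 min after addition of P1vir, a virulent form of the transducing phage P1, at a multiplicity of infection of 10. Each of the 8 groups of strain and condition held 2 libraries, labelled as experiments 1 and 2. Host genes received 327077 to 691512 counts per library (median 554828.5), and 2560 of 4497 host genes had enough counts to be tested. Phage genes received 435 to 6625 counts per library. In 15 libraries the deposited summary gives 94.49 to 98.8% mapping to the host; in the hfq mutant at 20 min, replicate 2, it gives 7.46%, with an rRNA fraction of 55.65% against 94.5 to 95.42% elsewhere and the lowest host total.

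The deleted gene was measured first. The hfq gene (b4172) had 234 to 447 counts in the 8 wild-type libraries and 0 to 5 in the 8 mutant libraries, a mean of 485.3 against 3.66 CPM. Its neighbours hflX, hflK and hflC had mutant means of 216.2, 322.7 and 241.7 CPM against wild-type means of 533.4, 706.6 and 502.1 CPM. The gene dksA, for a transcription factor of the stringent response that the growth protocol names as the mutated gene, had 124 to 216 counts in the mutant libraries and 151 to 333 in the wild type. On these values the mutant libraries lack hfq and not dksA.

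Without phage, the hfq mutant carried more RNA for peptide and amino acid uptake and less for surface adhesins and nucleotide synthesis than the wild type. In the list of genes linked to the small RNA GcvB, most of them for amino acid and peptide transport, 14 of 29 tested members were higher and none was lower (18 higher when adjusted over the list alone). They included oppA, the peptide-binding protein of the oligopeptide transporter (log2 fold change 2.13, SE 0.166, adjusted p = 1.18e-06), dppA (1.92, SE 0.221) and dppB (3.24, SE 0.432). This list passed the camera test (adjusted p = 1.03e-16) and did so with an estimated correlation (adjusted p = 0.0198). The adhesin gene flu (antigen 43) had 89.74 CPM ± 3.59 (SD, n = 2) in the mutant and 1357 ± 60.1 in the wild type, a log2 fold change of -3.91 (adjusted p = 3.19e-08), and fimA, the main subunit of type 1 fimbriae, was lower by the same measure (-3.37, SE 0.258). These were the 2 members called among 4 tested in the biofilm and fimbriae list (camera adjusted p = 7.73e-08; adjusted p = 0.0198 with an estimated correlation).

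In the same comparison, 13 of 29 purine and pyrimidine synthesis genes were lower in the mutant and none was higher (15 lower when adjusted over the list alone; camera adjusted p = 2.58e-06; adjusted p = 0.0198 with an estimated correlation). Among them carA and carB, for the carbamoyl phosphate synthetase that feeds pyrimidine and arginine synthesis, had log2 fold changes of -1.71 (SE 0.342) and -1.68 (SE 0.317) and codA -1.05. Of 37 genes for alternative sugars 11 were lower and 2 higher, with malT, the maltose regulator, at -1.55 (SE 0.249) and manZ at -1.43 (camera adjusted p = 0.00132; adjusted p = 0.366 with an estimated correlation). Of 36 Fur-regulated iron uptake genes 5 were lower and none was higher, among them the siderophore receptor genes fiu (-2.93, SE 0.748) and fepA (-2.56, SE 0.656); camera gave an adjusted p = 0.000404, and the adjusted p = 0.697 with an estimated correlation. DESeq2 called neither fiu nor fepA. The ferric citrate receptor gene fecA, outside that list's count, had 445.5 CPM ± 356 (SD, n = 2) in the mutant and 3550 ± 135 in the wild type (log2 fold change -2.98, adjusted p = 0.0107).

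Other single genes with large differences were chiP, the chitoporin gene (3.94, SE 0.57), leuC of leucine synthesis (2.40, SE 0.445), alaE, an alanine exporter gene (2.97), and pqqL (2.20), all higher in the mutant. The asparagine synthetase gene asnA (-3.76, SE 0.561) and the cystine transporter gene tcyP (-3.45, SE 0.526) were lower. Among porins ompF was higher (1.42, SE 0.142) and tsx lower (-1.26, SE 0.147). The envelope protease gene degP (-1.22) and the chaperone gene fkpA (-0.68) were lower in a sigma E list with 4 of 36 members lower. Malate dehydrogenase mdh (1.496) and malate synthase aceB (1.44) were higher. The SOS list (uvrB 0.97; 2 of 26 higher) and the flagella list (fliC 1.61; 1 of 17 higher) passed camera with adjusted p = 0.0105 and 0.0484. With an estimated correlation the adjusted p was 0.247 for SOS and 0.697 for flagella, and with the replicate block the flagella list had an adjusted p = 0.0611.

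In all, 354 of 2560 genes differed between the strains without phage at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 157 higher and 197 lower in the mutant, and 172 of them by at least 2-fold. Host rRNA rows held 5.95% ± 0.66 of the counts in the mutant and 3.28% ± 0.05 in the wild type (SD, n = 2). At 0, 10 and 20 min after phage addition they held 4.61, 6.8 and 7.27% in the mutant and 2.79, 2.51 and 2.98% in the wild type. The rRNA fraction in the deposited summary, without phage, was 94.62 and 94.69% in the mutant and 94.57 and 95.1% in the wild type. The counts on rRNA rows therefore do not measure the rRNA content of the cells. The genes oppA, dppA, dppB, flu, fimA, carB, malT, chiP, leuC, asnA, tcyP, ompF, tsx and mdh were called whichever library was left out. The call of each other gene named for this comparison was lost in at least 1 case. DESeq2 called 188 genes, with fiu, fepA, fliC and pqqL not among them. Leaving out wild-type replicate 1 or 2 gave 131 or 126 and mutant replicate 1 or 2 gave 219 or 123. The replicates came from experiments whose cultures the labels do not describe further, so p-values measure the spread between these samples.

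The strain difference was measured again, in separate libraries, at 0, 10 and 20 min after phage addition. Of the GcvB-linked genes 15, 17 and 13 of 29 were higher in the mutant and none was lower at any of these times (17, 19 and 15 when adjusted over the list alone; camera adjusted p = 4.79e-14, 6.33e-20 and 6.22e-14). The adjusted p with an estimated correlation was 0.034, 0.0256 and 0.0563. The gene oppA kept a log2 fold change of 2.13, 2.53 and 2.39 at 0, 10 and 20 min, with 7387 CPM ± 1040 in the mutant and 1284 ± 176 in the wild type at 10 min (SD, n = 2). The flu and fimA genes were lower at each time (flu -3.72, -3.59 and -3.37), and fimE, a recombinase gene of the same 4-member list, was higher at 0 min (1.95, adjusted p = 0.0354), with camera adjusted p = 6.42e-07, 4.35e-05 and 1.58e-05 for their list and adjusted p = 0.034, 0.0564 and 0.0563 with an estimated correlation.

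Purine and pyrimidine genes lower in the mutant numbered 8, 12 and 3 of 29 at 0, 10 and 20 min, with 0, 1 and 1 higher (camera adjusted p = 6.38e-06, 7.73e-06 and 0.0401; adjusted p = 0.034, 0.0319 and 0.394 with an estimated correlation). The gene carA had -1.996 at 0 min and -2.08 at 10 min, and carB -1.56 at 20 min. Sugar genes lower in the mutant numbered 8, 15 and 13 of 37, with 0, 2 and 1 higher (camera adjusted p = 0.00581, 1.18e-05 and 1.8e-05; adjusted p = 0.532, 0.159 and 0.181 with an estimated correlation). The mannose transporter gene manZ had log2 fold changes of -1.86, -2.49 and -2.27, and malT had -1.52 at 0 min. Of the iron uptake genes 5 of 36 were lower at 0 min, among them entH (-4.23) and fepA (-2.52), with camera adjusted p = 0.000214 and adjusted p = 0.917 with an estimated correlation. At 10 min the list had no called member (adjusted p = 0.233). At 20 min feoA, for ferrous iron uptake, was the member called and was higher (1.99; list adjusted p = 0.999).

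At 10 min the sulphate assimilation genes cysJ (-4.22, SE 0.504), cysI (-3.27, SE 0.541) and cysK (-2.04, SE 0.274) were lower in the mutant, as were tcyP (-4.29) and asnA (-4.03). At the same time cspA, a major cold shock protein gene, was 1.47 higher on the log2 scale and the RNA helicase gene deaD 1.52 higher, while cspC (-1.87) and cspE (-1.11) of the same list were lower (list adjusted p = 0.698). In the porin list ompF (0.90) was higher and tsx (-1.05) and lpp (-1.25) were lower. By camera this list had an adjusted p = 0.0627, 0.0343 with the replicate block and at least 0.462 with an estimated correlation. At 20 min lysC (-3.03, SE 0.453) and thrC (-1.81, SE 0.304) of the aspartate family were lower, as were betI (-3.15), asnA (-3.91) and gatZ (-1.66). Of 18 TCA cycle genes 6 were lower at 20 min, among them fumA (-1.61) and sucA (-1.20), and none was higher (camera adjusted p = 0.00594; adjusted p = 0.508 with an estimated correlation). The respiration list (nuoA -0.65; 2 of 31 lower) and the amino acid list (9 of 55 lower, 1 higher) had camera adjusted p = 0.00651 and 0.0373. With an estimated correlation these were adjusted p = 0.672 and 0.508, and with the replicate block the amino acid list had an adjusted p = 0.0631. The genes cspA (1.52) and deaD (1.65) were higher in the mutant at 20 min, and cspC (-1.58) and cspE (-1.24) lower (list adjusted p = 0.742).

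At 0 min 316 genes differed between strains (149 higher, 167 lower in the mutant), at 10 min 440 (195 higher, 245 lower) and at 20 min 360 (171 higher, 189 lower). Among the 2560 genes 57 were called higher and 83 lower in the mutant in each of the 4 conditions, and no gene was called with opposite signs. Independent lists of these sizes would share 0.046 and 0.091. The 4 comparisons are not independent, since they use the same strains and 1 fit with a shared spread per gene. The calls of fepA and fimE at 0 min and of carB, nuoA and feoA at 20 min were lost in at least 1 case of a left-out library. DESeq2 did not call fepA or fimE at 0 min or nuoA or feoA at 20 min. With library size alone as scaling the 20 min split was 139 higher and 234 lower. DESeq2 called 174, 238 and 203 genes; leaving out 1 library gave as few as 143 at 0 min (mutant replicate 2; 152 and 150 without wild-type replicate 1 or 2), 215 at 10 min (mutant replicate 2; 250 without wild-type replicate 1) and 185 at 20 min (mutant replicate 2, the library with 7.46% mapping; 192 and 199 without wild-type replicate 1 or 2).

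**Figure D1:**
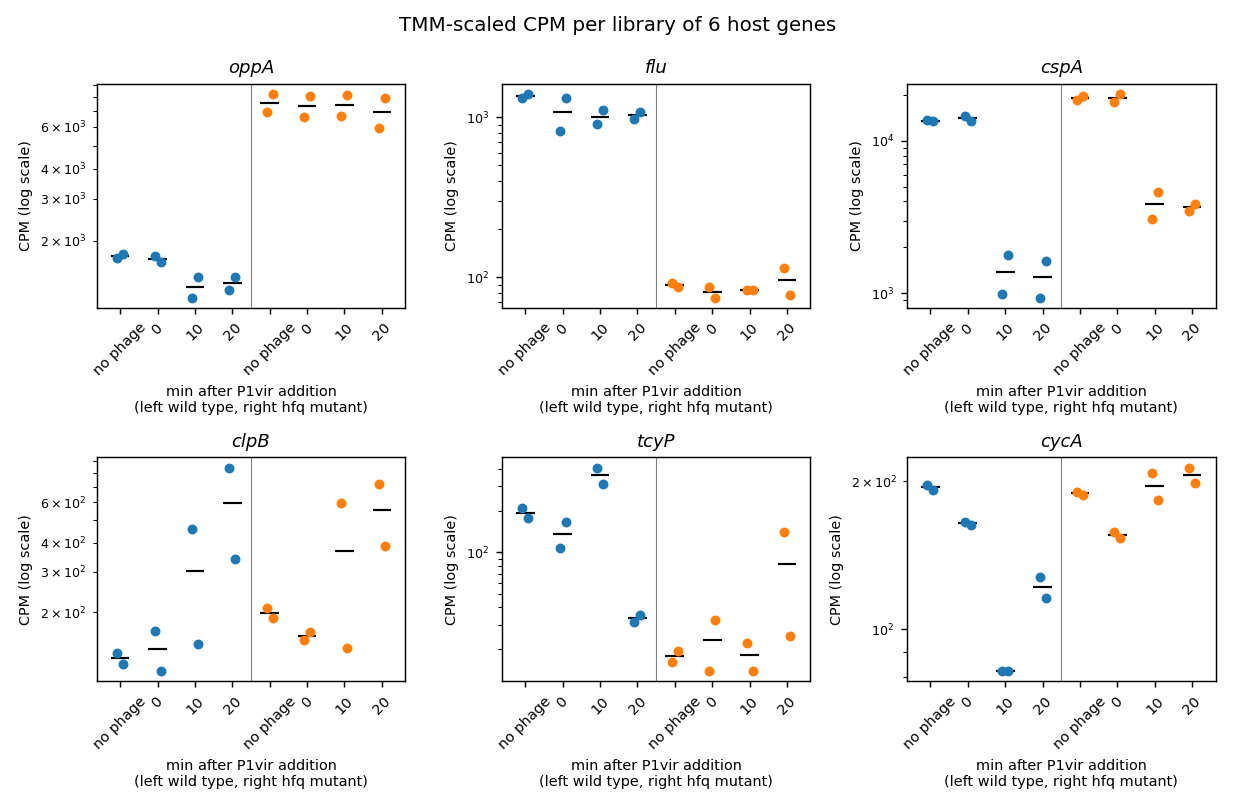
Points are the 2 libraries of each group and bars their mean, in TMM-scaled CPM on log axes, for 6 host genes across strain and time. oppA lies higher and flu lower in each mutant library than in each wild-type library, and cspA lies lower in the libraries from 10 and 20 min than in those from 0 min or without phage, in both strains.

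The response to phage addition was compared with the culture of the same strain without phage. No uninfected culture was sampled at 10 or 20 min, so infection and time in culture are not separated. At 0 min no gene passed the threshold in either strain by edgeR or by DESeq2, with 65 genes at an unadjusted p under 0.05 in the wild type and 82 in the mutant by edgeR; without wild-type 0 min replicate 2 the wild-type count was 1. The flagella list of the wild type passed camera at 0 min without a single called member (median log2 fold change 0.95, adjusted p = 1.62e-05; adjusted p = 0.9 with an estimated correlation).

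At 10 min after phage addition wild-type cells had less RNA of the cold shock genes cspA and cspG and more of cysP, cysJ, cysQ and cysK, genes of sulphate assimilation and cysteine synthesis. These 2 cold shock genes had log2 fold changes of -3.29 (SE 0.273, adjusted p = 1.1e-05) and -4.00 (SE 0.475), and cspA went from 13510 CPM ± 187 to 1384 ± 558 (SD, n = 2). With deaD (-1.13) these were 3 of the 7 tested cold shock genes, none of which was higher (camera adjusted p = 2.23e-05; adjusted p = 0.108 with an estimated correlation). Among the genes that rose were cysP (3.67, SE 0.751), cysJ (2.68, SE 0.404), cysQ (2.66, SE 0.58) and cysK (1.99, SE 0.27), soxS, the superoxide response regulator (2.19), and glnH, a glutamine-binding protein (1.64). The glycine and alanine transporter cycA (-1.24, SE 0.15) and kgtP (-1.07) were the called members of the GcvB-linked list, both lower (camera adjusted p = 0.000839; adjusted p = 0.474 with an estimated correlation). Sugar genes went both ways, with 4 of 37 higher (manZ 1.34, gatY 1.67) and 2 lower (glpD -1.70).

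By camera, the sugar list (adjusted p = 0.000926), the amino acid list (6 of 55 higher, none lower; 0.000316), heat shock (0 of 25 called; 0.0183) and flagella (0 of 17 called; 0.00981) stood higher at 10 min in the wild type. RNA turnover (rho -0.72; 1 of 17 lower; 0.0183) and iron uptake (0 of 36 called; 0.0141) stood lower. With an estimated correlation the adjusted p was 0.474 for sugar, 0.234 for amino acid, 0.872 for heat shock, 0.587 for flagella, 0.474 for RNA turnover and 0.873 for iron uptake. In the list of porins and receptors ompF (0.69) and lpp (0.87) were higher. By camera their list had an adjusted p = 0.0997, 0.0406 with the replicate block and at least 0.462 with an estimated correlation. The calls of cspA, cspG, cycA, cysK and glpD held whichever library was left out and those of the other genes named did not; with 0 min as the reference cysQ and lpp were not called. In total 75 genes passed the threshold, 47 higher and 28 lower. The replicate block raised this to 181, DESeq2 gave 39, and leaving out no-phage replicate 1 or 2 or 10 min replicate 1 left 6, 5 and 10.

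At 20 min genes of the heat shock list were higher in the wild type. Of 25 RpoH-dependent genes 11 rose and none fell (20 when adjusted over the list alone), among them the small chaperones ibpA (2.56, SE 0.629) and ibpB (3.25, SE 0.898) and the disaggregase clpB (2.24, SE 0.604). The list passed camera (adjusted p = 5.11e-08; adjusted p = 0.338 with an estimated correlation). The SOS genes recN (1.89, SE 0.301), recA (1.13, SE 0.219) and sulA (1.64, SE 0.445) rose with 2 others of 26, and dinG, named after its values were seen, fell (-0.97; camera adjusted p = 0.00342; adjusted p = 0.271 with an estimated correlation). Cold shock genes stayed low, with cspA at -3.40 and cspG at -4.21; deaD (-1.53) and, named after its values were seen, rbfA (-0.72) fell and cspC rose (0.90), 4 lower and 1 higher of 7 (camera adjusted p = 0.000187; adjusted p = 0.207 with an estimated correlation). Of 54 ribosomal protein genes 6 were called lower (rplF -0.41) and none higher (camera adjusted p = 1.42e-07, and 0.271 with an estimated correlation). RNA turnover genes rho (-0.70), rnr (-0.66) and pnp (-0.69) fell with 2 others of 17 (camera adjusted p = 0.00333; adjusted p = 0.271 with an estimated correlation).

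Lists of metabolic genes had members called in both directions in the wild type at 20 min, and none of the 3 passed with an estimated correlation (adjusted p = 0.271 for each). Of 18 TCA cycle genes 5 rose, among them sucC (1.07) and sucA (1.02), and lpd fell (-0.43; 8 and 1 when adjusted over the list alone; camera adjusted p = 0.00105). Of 37 sugar genes 8 rose, with gatZ (1.51) and gatC (1.69) of galactitol uptake and catabolism among them. Another 2 fell, glpD (-1.95) among them (10 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.00149). Of 55 amino acid genes 6 rose (thrA 1.54) and cysI fell (-2.20; 10 and 2 when adjusted over the list alone; adjusted p = 0.00105). Flagella (0 of 17 called; adjusted p = 0.000202), iron uptake (fhuE -1.67; adjusted p = 0.002) and LPS core synthesis (waaS -1.05; adjusted p = 0.0488, and 0.0546 with the replicate block) had an adjusted p of 0.271, 0.59 and 0.271 with an estimated correlation. Outside the lists pstC of phosphate uptake (2.34) and soxS (2.50) rose and tcyP fell (-2.54). Whichever library was left out, cspA, cspG, deaD, gatZ, glpD, sucC and thrA were called, which held for none of the other genes named, the heat shock and SOS genes included. Library size alone did not call dinG, lpd, rplF, rbfA or fhuE. DESeq2 did not call clpB, cspC, dinG, rbfA or waaS, and 0 min as the reference did not call cspC, cysI, dinG, fhuE, ibpB, rplF, sulA or waaS. In total 251 genes passed the threshold, 126 higher and 125 lower. The replicate block gave 420, DESeq2 84 and library size alone 184 higher and 66 lower, with the median of all genes at 0.15; without no-phage replicate 1 or 2 or 20 min replicate 1 or 2 the count was 20, 44, 27 and 138.

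In the hfq mutant fewer genes passed the threshold. At 10 and 20 min cspA (-2.32, SE 0.261; -2.38, SE 0.262) and cspG (-3.47, SE 0.392; -3.89, SE 0.434) were lower, and these were the called members of the cold shock list (2 of 7 lower, none higher, at each time; camera adjusted p = 1.06e-06 and 1.66e-06; adjusted p = 0.0406 and 0.0615 with an estimated correlation). The regulator soxS (3.27, SE 0.6; 3.08, SE 0.634), glnH (1.87; 1.74) and glutamine synthetase glnA (1.34; 1.29) were higher at both times. The methionine transporter gene metI (1.01) was higher at 10 min and pntA, of the transhydrogenase, at 20 min (1.38). At 20 min glycogen phosphorylase glgP (-1.24), suhB (-1.10), the nitric oxide sensor nsrR (-1.14), rnr (-0.92) and rho (-0.75) were lower.

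Heat shock genes had no called member over all genes in the mutant, but 1 of 25 at 10 min and 19 of 25 at 20 min were higher when adjusted over the list alone, with medians of 0.62 and 1.31 (camera adjusted p = 1.76e-05 and 3.03e-16; adjusted p = 0.992 and 0.621 with an estimated correlation). At 20 min flagella stood higher (0 of 17 called; adjusted p = 0.000222), and ribosomal proteins (0 of 54 called; adjusted p = 6.65e-05) and RNA turnover (2 of 17 lower; adjusted p = 0.0131) stood lower. With an estimated correlation these were adjusted p = 0.623, 0.719 and 0.623. By camera the porin list had an adjusted p = 0.134, 0.0448 with the replicate block and at least 0.462 with an estimated correlation. Whichever library was left out, cspA was called at both times and cspG at 10 min, which held for none of the other genes named. With 0 min as the reference metI at 10 min and soxS at 20 min were not called, nor was nsrR in DESeq2. Counts were 14 genes at 10 min (7 higher, 7 lower) and 21 at 20 min (7 higher, 14 lower), which the replicate block raised to 56 and 99. The 10 min count was 25 with library size alone, 32 with no filter on low counts and 24 with 0 min as the reference, and the 20 min count was 56 with no filter. Without no-phage replicate 1 or 2 the 10 min count was 3 and 4, and 3 or 34 without 10 min replicate 1 or 2; the 20 min count was 8 and 4 without no-phage replicate 1 or 2, and 1 or 16 without 20 min replicate 1 or 2.

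**Figure D2:**
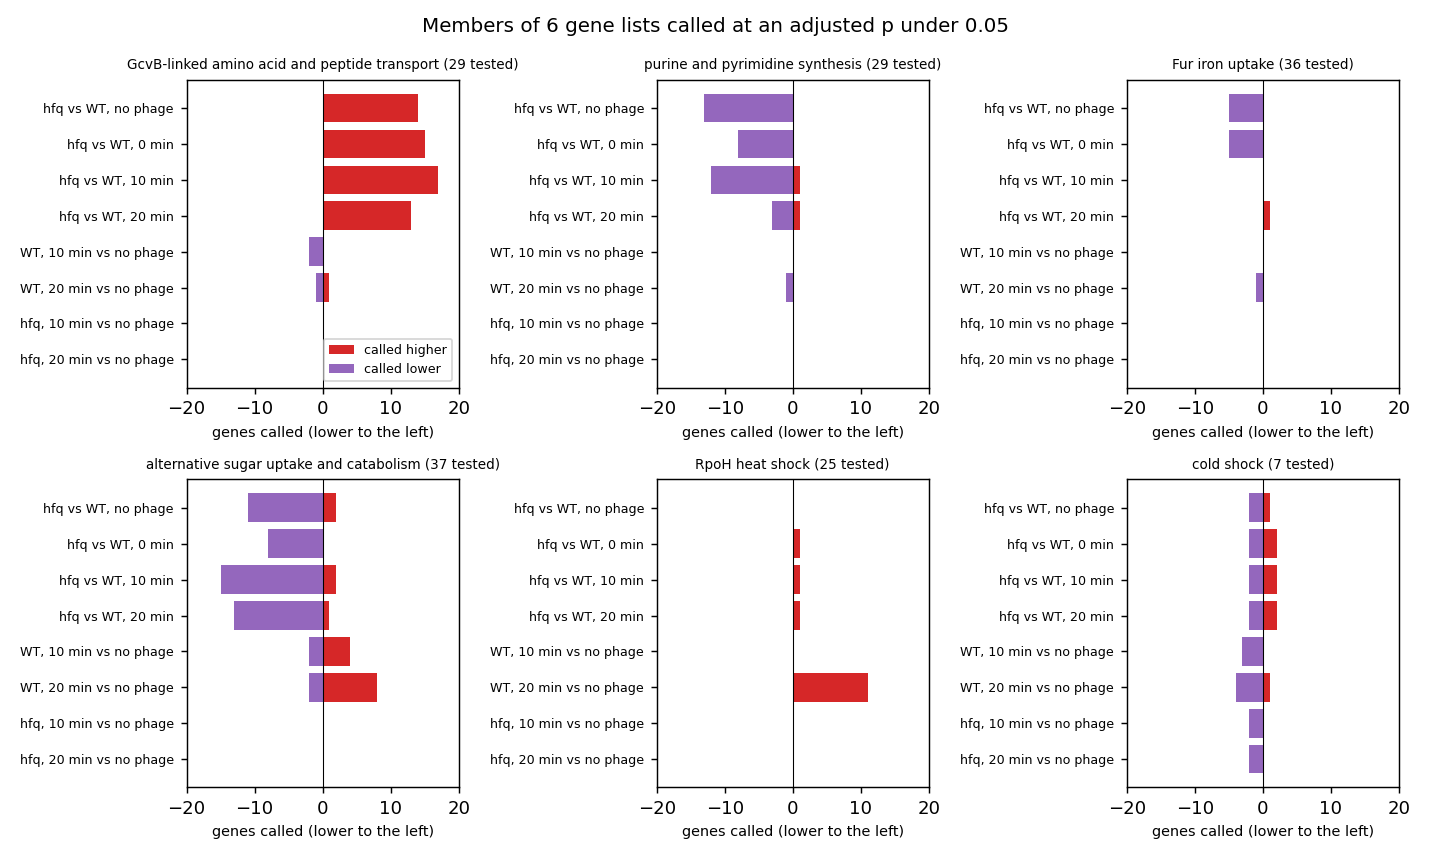
Bars give the number of members of 6 gene lists called higher (right) or lower (left) in 8 comparisons of host genes. The GcvB-linked list has 13 to 17 members higher in the mutant at each time, and the heat shock list has 11 members higher in the wild type at 20 min.

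Whether the strains responded differently was tested as the difference between their changes from no phage. At 10 min this called cycA alone (difference in log2 fold change 1.29, SE 0.204, adjusted p = 0.0338), which went from 194.7 CPM ± 3.21 to 82.23 ± 0.08 in the wild type and from 189.2 ± 1.72 to 195.9 ± 17.7 in the mutant (SD, n = 2). At 20 min it called tcyP alone (difference 4.92, SE 0.747, adjusted p = 0.0229), which went from 193.4 ± 24.4 to 33.27 ± 3.02 CPM in the wild type and from 17.75 ± 2.31 to 82.97 ± 82.2 in the mutant. Of the 251 genes called in the wild type at 20 min 228 had the same sign in the mutant, and 16 were called there with that sign, where independent lists would share 1.03. Both lists come from 1 fit with a shared spread per gene, so they are not independent. For the difference DESeq2 called 0 and 1 genes, and the replicate block 1 and 8. A block within each strain, chosen after the result was seen, called more genes at both times. The gene cycA was also not called with library size alone or with no filter on low counts, nor tcyP with 0 min as the reference. Leaving out any 1 library of the comparison ended the call of cycA, and leaving out any but mutant 20 min replicate 2 ended that of tcyP, whose difference was 3.03 without mutant 20 min replicate 1.

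Phage RNA was below 0.002% of counts at 0 min and rose with time in both strains. Shares are given without 3 phage tags that carried counts in uninfected cells. At 10 min phage genes held 0.156% ± 0.0838 of counts in the wild type and 0.139% ± 0.0453 in the mutant, and at 20 min 0.667% ± 0.475 and 0.439% ± 0.208 (SD, n = 2). Experiment 1 and 2 of the wild type at 20 min gave 1.00% (exact binomial 95% interval 0.978 to 1.03%) and 0.332% (0.316 to 0.349%), and those of the mutant 0.586% (0.566 to 0.607%) and 0.292% (0.274 to 0.311%). With all tags included the log2 ratio of mutant to wild type was 0.28 at 0 min, -0.08 at 10 min and -0.49 at 20 min, against spreads between replicates of 0.11, 0.67 and 1.17, which include the difference between experiments. The 0 min ratio rests mostly on the 3 tags and does not measure phage RNA. With all tags the 0 min shares were 0.089% in the wild type and 0.108% in the mutant, and those without phage 0.083% and 0.096%. Within experiments 1 and 2 the log2 ratio was 0.33 and 0.23 at 0 min, -0.26 and 0.20 at 10 min and -0.66 and -0.11 at 20 min. The 10 min ratio was 0.42 without wild-type replicate 1, -0.44 without wild-type replicate 2, -0.29 without mutant replicate 1 and 0.11 without mutant replicate 2. The 20 min ratio was 0.38 and -1.03 without wild-type replicate 1 or 2, and -0.98 and -0.12 without mutant replicate 1 or 2. No exact test of 2 against 2 libraries can give a p below 0.33. Without the 3 tags the 0 min ratio was 1.00, from 9 counts in the wild type and 15 in the mutant. Within experiments 1 and 2 the ratio without these tags was 1.464 and 0.459 at 0 min, -0.327 and 0.155 at 10 min and -0.775 and -0.186 at 20 min. Uninfected libraries held 4 and 1 counts on the remaining tags in the wild type and the mutant, 0.00039% and 0.00007%, and the libraries with no such count allow shares of up to 0.000444% and 0.000551%. Intervals and limits cover counting error alone.

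**Figure D3:**
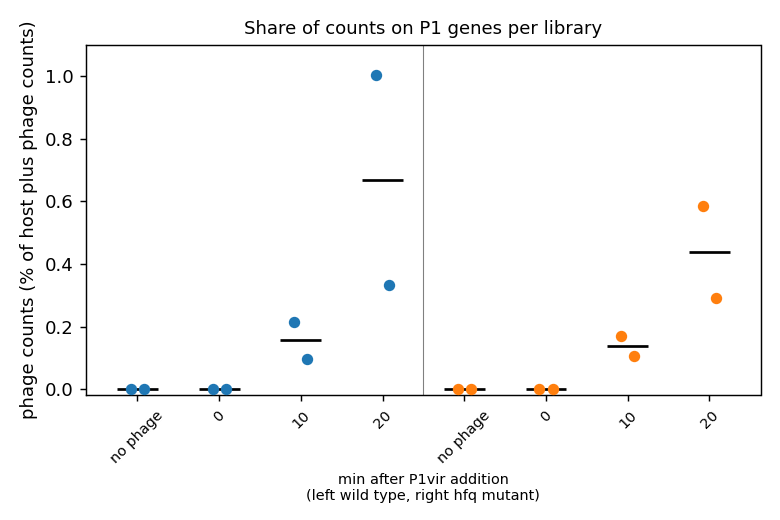
Points are libraries and bars group means of the share of counts on phage genes, in percent of host plus phage counts, without the 3 tags seen in uninfected cells. At 20 min the wild-type libraries lie at 1.00 and 0.332% and the mutant libraries at 0.586 and 0.292%.

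Phage genes were tested one by one relative to host RNA, over the 46 of 117 tags with enough counts. From 0 to 10 min 41 tags rose and none fell in each strain. From 10 to 20 min 18 rose and none fell in the wild type (median log2 fold change 2.06), and 2 rose and none fell in the mutant (median 1.66). The tag P1_gp093 went from 221.8 to 870.2 host-scaled CPM in the wild type, and P1_gp095 from 133.9 to 558.6. Between strains no tag differed at 10 or 20 min by edgeR, at an adjusted or an unadjusted p under 0.05, nor by DESeq2. The median log2 fold change of mutant over wild type was 0.00 at 10 min and -0.53 at 20 min over the 46 tags. Over the 43 tags without counts in uninfected cells it was -0.07 and -0.55, with 39 of 43 negative at 20 min. No tag differed between strains in its change from 10 to 20 min by either tool.

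On simulated counts without the replicate block the phage test at 20 min recovered 0% of 2-fold and 16.7% of 4-fold changes, so the lack of calls between strains does not exclude such differences. The replicate block called 3 tags lower in the mutant at 20 min, and 38 and 35 tags from 10 to 20 min in the wild type and the mutant. DESeq2 called 15 and 0 tags from 10 to 20 min, host plus phage totals as library size 10 and 0, a minimum of 1 count 5 and 0, and the fit without the 3 tags seen in uninfected cells 0 and 0; scaling among phage genes called 0 higher and 2 lower in the wild type and 0 higher and 5 lower in the mutant. Without wild-type 10 min replicate 1 or 2 or 20 min replicate 1 or 2 the wild-type count was 6, 0, 0 and 37, and leaving out any 1 library took the mutant count to 0. The deposited tables and the reference used here do not pair phage tags with gene names, so the 7 lists of phage functions could not be matched.

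Of the 27 host lists 12 passed the camera test in none of the 12 comparisons (smallest adjusted p 0.0627). They were Hfq-associated small RNAs (4 tested), Hfq-independent stable RNAs (6), sigma E (36), Cpx and Psp (12), RpoS general stress (18), acid resistance (3), porins and receptors (11), RyhB-repressed iron-using genes (17), OxyR and SoxRS (20), DNA replication (28), restriction and defence (6) and resident prophage genes (7). Single members of such lists did differ between strains. The small RNA glmZ (mean log2 fold change -1.88), csrB of the stable RNAs (-1.64) and hdeA of acid resistance (-2.30) were called lower in the mutant in each of the 4 conditions. Other members called lower in each included degP of the sigma E list (-1.14) and tsx of the porin list (-1.11). Members called higher in each included ompF (1.05) and chiP (2.24) of the porin list and dnaA of DNA replication (0.675). Of 27 listed Hfq-associated small RNAs 24 were matched and 4 had enough counts to be tested.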

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

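The tests of the 3 phage tags, the thinning with a replicate block and the block within each strain were chosen after the result was seen; the other tests of the number of called genes were not. The strains' changes from no phage to 10 min differed in cycA, a GcvB-linked transporter gene, by 1.29 on the log2 scale (edgeR quasi-likelihood test, adjusted p = 0.0338), and those to 20 min in tcyP by 4.92 (adjusted p = 0.0229). The 2 mutant libraries at 20 min had 141 and 24.9 CPM of tcyP. The cycA call was absent with library size alone (adjusted p = 0.0694), with no filter on low counts (0.108), in DESeq2 (1) and in each of the 9 fits that left out a library of the comparison or mutant 20 min replicate 2 (0.0527 to 0.314). The tcyP call was absent with 0 min as the reference (adjusted p = 0.104) and in 7 of the 8 fits that left out a library of the comparison (0.0605 to 0.36), the exception being mutant 20 min replicate 2.

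Gene lists also differed between strains in their change by camera, with few or no single members called. At 10 min these were amino acid synthesis, lower in the mutant (median difference -0.30, adjusted p = 0.018), iron uptake, higher (0.69), GcvB-linked genes, higher (0.33), and flagella, lower (-0.78), the last 3 at an adjusted p = 0.0316. At 20 min they were iron uptake, higher (1.31, adjusted p = 1.06e-05), TCA cycle, lower (-0.47, 9.04e-05), amino acid synthesis, lower (-0.38, 0.00904), purine and pyrimidine synthesis, higher (0.16, 0.0328), and SOS, lower (-0.34, 0.0411). With an estimated correlation the adjusted p was 0.997 for each list at 10 min, 0.851 for iron uptake and 0.346 for the other 4 lists at 20 min. Without mutant 20 min replicate 2 it was 0.15 for purine and pyrimidine synthesis and 0.0952 for SOS.

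At 20 min 251 genes were called in the wild type and 21 in the mutant, while the test of the difference called 1. With the replicate block these counts were 420, 99 and 8, and with a block within each strain 539, 148 and 31. Lower depth of the mutant libraries was argued against: with wild-type libraries thinned to the mutant totals of the same experiment, the median count over 20 draws was 226 (205 to 246), and 374.5 (355 to 392) with the replicate block. Equally large responses in both strains, with genes picked by their wild-type values, remain open. Over 200 genes picked in 1 wild-type experiment, the ratio of the mutant median to that of the other wild-type experiment was 0.739 and 0.566, and 0.419 and 0.497 with the picking experiment exchanged, which spans the 0.67 set beforehand. The ratio of 0.739 set mutant experiment 1 against wild-type experiment 2. Matched by experiment, the ratios were 0.419 in experiment 1 and 0.566 in experiment 2, both under 0.67. This matching was chosen after the values were seen. A smaller response of the mutant, which the design names, may underlie the difference in counts. Under the rule set beforehand it stays open beside selection, since the highest ratio was 0.739. Between replicates the SD of log2 CPM was 0.507 without phage and 0.598 at 20 min in the mutant. In the wild type these SDs were 0.404 and 0.475. Whether this larger spread lowers the mutant count was not tested beyond the fits with a block.

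Phage tags P1_gp008, P1_gp018 and P1_gp019 carried means of 456.5, 61 and 29 counts in the 4 uninfected libraries, which should hold no phage. Carry-over from infected libraries was argued against: the other tags held 5 counts there, where their proportion to these 3 tags at 20 min would need 13730.1. Reads from host sequence shared with these tags are a candidate explanation: at 20 min their level relative to host counts was 0.99 times the uninfected level (0.829 to 1.132 by library), while the other tags stood 2207.8 times higher. No sequence was at hand to look for a match, and no biological explanation was tested.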

How the results depend on the processing

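The fits without rRNA and tRNA genes, without mutant 20 min replicate 2 throughout, with a block within each strain and without the background tags were chosen after the result was seen. Counts moved by over 1.5 times under many settings, no named gene changed direction under any alternative run, and the cause was not tested except where stated. Of 136 fold changes of single genes, all kept their direction and their side of the threshold under the replicate block and under RLE scaling, 6 lost their call with library size alone, 1 with no filter on low counts, 15 of 123 in DESeq2 and 13 of 65 with 0 min as the reference. DESeq2 gave no adjusted p for the rest of the 136, so these were not called by it either and are not among the genes listed as lost. The phage test between strains at 20 min, without the block, recovered 0% of 2-fold changes on simulated counts, and depth and the spread between experiments were not separated as limits.

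With the replicate block 181 genes were called in the wild type at 10 min and 420 at 20 min, 56 and 99 in the mutant, and 8 for the difference between strains at 20 min; phage tags were 3 for mutant against wild type at 20 min, and 38 and 35 from 10 to 20 min in the wild type and the mutant. The block took flagella without phage (adjusted p = 0.0611), amino acid synthesis between strains at 20 min (0.0631) and LPS core in the wild type at 20 min (0.0546) past the threshold upward, and brought porins between strains at 10 min (0.0343), in the wild type at 10 min (0.0406) and in the mutant at 20 min (0.0448), and ribosomal proteins in the difference at 20 min (0.0454), below it. It changed no other call of a list or named gene. With an estimated correlation the porin list had a camera adjusted p of at least 0.462 in each comparison. With a block within each strain the counts were 542 and 511 between strains without phage and at 0 min, 290 and 539 in the wild type, 87 and 148 in the mutant, and 2 and 31 for the differences.

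DESeq2 called 188, 174, 238 and 203 genes between strains, 39 and 84 in the wild type, 0 for the difference at 10 min, and 0 phage tags from 10 to 20 min in the mutant. With a log2 fold change of at least 1, which can only lower a count, these were 172, 163, 206 and 166 between strains, 45 and 119 in the wild type and 9 in the mutant at 10 min. The mutant at 10 min had 25 genes with library size alone, 32 with no filter on low counts, 24 with 0 min as the reference and 25 without rRNA and tRNA genes, and the mutant at 20 min 56 with no filter. The difference at 10 min had 0 genes with library size alone and 0 with no filter (114 at an unadjusted p under 0.05 in edgeR as reported), and that at 20 min 0 with 0 min as the reference. Phage tags from 10 to 20 min in the wild type and mutant were 2 and 5 with TMM among phage genes, 10 and 0 with host plus phage totals, 5 and 0 with at least 1 count, and 0 and 0 without the background tags, where the log2 share ratio at 0 min was 1.00.

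With an estimated correlation these lists passed the threshold no longer. Between strains without phage: iron uptake and flagella (0.697), SOS (0.247), sugar (0.366). At 0 min: iron uptake (0.917), sugar (0.532). At 10 min: biofilm (0.0564), sugar (0.159). At 20 min: GcvB-linked and biofilm (0.0563), purine and pyrimidine (0.394), amino acid and TCA (0.508), respiration (0.672), sugar (0.181). In the wild type: flagella at 0 min (0.9); at 10 min heat shock (0.872), iron uptake (0.873), GcvB-linked, sugar and RNA turnover (0.474), flagella (0.587), amino acid (0.234), cold shock (0.108); at 20 min heat shock (0.338), iron uptake (0.59), cold shock (0.207), and flagella, SOS, ribosomal, amino acid, TCA, sugar, LPS and RNA turnover (0.271). In the mutant: heat shock at 10 min (0.992), and at 20 min heat shock (0.621), flagella and RNA turnover (0.623), ribosomal (0.719), cold shock (0.0615). In the differences: 0.997 at 10 min for 4 lists, 0.851 for iron uptake and 0.346 for 4 lists at 20 min.

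Leaving out 1 library, with the lone sample assumed to vary like the other groups, gave 123 to 353, 143 to 329, 215 to 447 and 185 to 284 genes between strains, 0 to 1, 5 to 106 and 20 to 265 in the wild type, 0 to 0, 3 to 34 and 1 to 16 in the mutant, and 0 to 0 and 0 to 1 for the differences, where fewer libraries are fitted. Phage tags were 35 to 43 and 0 to 37 in the wild type, 31 to 40 and 0 to 0 in the mutant and 0 to 0 in the other phage comparisons. The log2 share ratio was 0.2 to 0.351 at 0 min, -0.444 to 0.416 at 10 min and -1.03 to 0.38 at 20 min. Without mutant 20 min replicate 2 the lists for SOS and for purine and pyrimidine in the difference at 20 min had an adjusted p = 0.0952 and 0.15.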

Other observations

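The heat shock and phage values were set side by side after both had been seen; the test of cold-induced genes was chosen beforehand. Heat shock RNA and phage RNA were both higher in experiment 1 than in experiment 2 at 10 and 20 min after phage addition. The mean log2 CPM of the 25 heat shock genes was 8.45 and 7.77 in wild-type experiments 1 and 2 at 10 min and 9.04 and 8.27 at 20 min, and 8.52 and 7.60 in the mutant at 10 min and 8.90 and 8.24 at 20 min. Phage shares in the same libraries were 0.215 and 0.0962%, 1.00 and 0.332%, 0.171 and 0.107%, and 0.586 and 0.292%. Without phage the heat shock means were 7.68 and 7.60 in the wild type and 7.64 and 7.24 in the mutant.

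The fall of cspA and cspG between the no phage samples and 10 min was weighed against handling of the cultures, since both are induced by cold. If the cultures stood cooler at the 0 min samplings, other cold-induced genes outside the list should fall with them. Over 11 tested of 12 such genes, among them nusA, infA, infB, infC and hns, the median log2 fold change at 20 min was -0.24 in the wild type (7 negative, 3 called lower) and -0.002 in the mutant (6 negative, 1 called lower). At 10 min, when cspA and cspG had already fallen, the median was 0.09 in the wild type (5 negative, 2 called lower). In the mutant it was -0.02 at 10 min (6 negative, 0 called lower). The camera test of these genes passed an unadjusted 0.05 at 20 min in the wild type and not in the mutant, and at 10 min in neither strain. Members went both ways at 20 min, from -1.22 to 0.43 in the wild type and from -1.92 to 0.29 in the mutant. Cooler cultures at 0 min remain a candidate explanation that these values neither exclude nor bear out in both strains. An effect of infection, and of time in culture, stays open too and was not tested, since no uninfected culture was sampled later.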
